A study of Arabidopsis thaliana with 6 samples.

How the data were processed

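Expression was measured in leaves of Arabidopsis thaliana Col-0 plants, 28 days old and grown in sterile 0.5 L glass jars, with 33 plants per experiment. Per the labels' protocols, total RNA of 3 independent extracts was pooled for each array, labelled with biotin and hybridised to an Affymetrix whole-genome array. Spray was distilled water or 0.2% Tween 20 (1.6 mM). Per the series' design text, experiments IA and IB were biological repetitions collected at 1 h and experiment II was collected at 2.5 h. Samples were assigned to groups by their titles. The treatment text of the labels did not follow the titles, naming water for the Tween samples as well and 2.5 h for the 1 h samples of IA, so the groups rest on the titles and on the design text.

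The deposited values are probe set signal intensities on a linear scale, which the authors made with MAS5 per the submitters' processing notes. The version and the parameters of MAS5 are not given in the sources used here. The deposited intensities appear scaled to 1 target, since the mean of each array between its 2nd and 98th percentiles was 100.008 or 100.009. Such global scaling sets the level of every array to the same mean, so a shift of most transcripts in 1 direction would not be seen. Detection calls were not used here. The table held 22810 probe sets for 6 arrays, of which 64 were Affymetrix controls and were left out of the tests. Among the arrays 0 columns were identical, and the highest correlation between log2 arrays was 0.977.

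Intensities were used as deposited, since the trimmed means were equal, and log2 values were taken after setting signals of 0 to 0.1. A probe set was tested if its signal reached the 40th percentile of its own array on at least 2 of the 6 arrays, which left 14345, of which 7739 had 1 gene. Signals near that percentile (20.6 to 23.9 units) carry more noise than bright ones, and folds of dim probe sets are the least certain. Names came from the GEO platform annotation, in which 13513 probe sets had 1 gene, 503 had several and 8730 had none. Of the probe sets with 1 gene, 13436 were matched through the gene identifier to the NCBI RefSeq annotation of assembly TAIR10.1. No gene was named from a probe set with several or none, and no coordinates are given because the annotation names no build for the probes. OPR1 and OPR2, the genes of the study's earlier Northern blots, had no probe set named here and are not reported here, and the same holds for many members of the gene lists.

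Tween 20 was compared with water in limma 3.58.1 under R 4.3.3 (statmod 1.5.0), with the experiment as a block, because the study compared Tween 20 with water within each experiment. The fits used eBayes with an intensity trend and Benjamini-Hochberg adjustment at 0.05. The 1 h fit used 4 arrays and left 1 residual degree of freedom, and the fit over 3 experiments used 6 arrays and left 2, to which the prior added 4.70 and 5.03. The 2.5 h effect and its difference from the 1 h effect were fitted on all 6 arrays, with the spread of the 1 h pairs standing for that of the 2.5 h pair. Error is given as SD over the 1 h pairs or as the SE of the fit. Pairing was checked on the deviations of arrays from the mean of their treatment arm over the 3 experiments. Arrays of the same experiment correlated at 0.576 (IA), 0.714 (IB) and 0.711 (II). All other combinations had negative values, which this centring favours. The pairing itself comes from the titles and the design text.

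Probe sets with a 2-fold difference, the study's criterion, were counted with no test. A filter chosen here required the brighter signal of the pair to lie at or above the 40th percentile of its array, and the study's own filter is not given in the sources used here. Overlaps of such sets were tested by two-sided Fisher's exact tests among the 13310 probe sets bright in all 3 pairs. Gene lists were tested by limma's camera with a preset correlation of 0.01, and beside it with an estimated correlation, adjusted over the lists tested. With an estimated correlation, camera uses the residual degrees of freedom of the fit, 1 at 1 h and 2 over 3 experiments. A small list can fail to pass there for that reason alone. Of 316 entries in 20 lists written before the data were examined, 59 had a probe set, 1 was left out because its code and symbol disagreed, and 5 lists had 3 or more tested members. A further 8 gene families were chosen after the values were seen and appear only among the other observations, and the result of 1 of them is not reported here.

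Genes named in the results follow rules set before the data were examined. They are, among probe sets with 1 gene, the 10 highest and 5 lowest mean folds among those 2-fold in both 1 h pairs, the same for the 2.5 h pair, the 10 with the highest smallest fold over the 3 pairs, the 5 highest and 5 lowest by the interaction statistic, and the 3 members of each list with the largest absolute statistic. Other genes are named only where this is stated.

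The fits were tested on simulated data with 200 of 14345 probe sets changed by 1.5-fold, 2-fold or 4-fold. With noise of each probe set's moderated variance, the fit over 3 experiments made 201 calls, 15.9% of them false, the 1 h fit 255 calls with 34.5% false and the 2.5 h fit 113 calls with 17.7% false. With variances drawn from the fitted prior, false calls were 5.22% of 115, 12.0% of 100 and 12.7% of 55. Changes of 4-fold were recovered in 98.5% and 97.0% of cases over 3 experiments under the respective noise models, in 100% and 92.4% at 1 h and in 95.5% and 69.7% at 2.5 h. Changes of 2-fold were recovered in 95.5% and 61.2% over 3 experiments, in 95.5% and 37.3% at 1 h and in 41.8% and 2.99% at 2.5 h. The share of false calls therefore exceeded the nominal level in the simulations, more so in the fits with 1 residual degree of freedom.

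Alternatives were median centring, quantile normalization, no filter, a filter at the 60th percentile, a pseudocount of 6.4 units (the 20th percentile of all signals), no block, no intensity trend and each experiment left out in turn. For lists, fry, another correlation and the removal of probe sets that may bind related genes were tried. Array weights, sets of equal size and the 8 families were added after the data were seen.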

Results

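Leaf RNA from 28-day-old Arabidopsis thaliana plants of the Col-0 ecotype was measured on 6 whole-genome Affymetrix arrays after foliar spraying with distilled water or with Tween 20. Tween 20 is a non-ionic detergent, applied here at 1.6 mM. Leaves were collected after 1 h in experiments IA and IB, which were biological repetitions, and after 2.5 h in experiment II. Each experiment gave 1 water array and 1 Tween array, so that the 1 h comparison rests on 2 pairs and the 2.5 h comparison on 1 pair without a replicate. Each array carried RNA pooled from 3 extracts, which hides the spread between extracts, and the number of arrays limits the precision of every value below. The median signal of an array lay between 36.5 and 40.5 units, and 14345 of the 22810 probe sets were bright enough to be tested. The arrays were made to separate fast and transient responses to the detergent from slower and lasting ones.

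After 1 h, some transcripts stood at least 4-fold above water on average over the repetitions. The named gene furthest above water was AT1G49000, 6.07-fold higher with Tween 20, with log2 folds of 2.1 in IA and 3.1 in IB (mean 2.60 ± 0.71, SD, n = 2). AT5G59170, which encodes an extensin-like cell wall protein, was 5.24-fold higher (2.39 ± 0.35), and AT1G22810, a transcription factor of the ERF family, was 4.54-fold higher (2.18 ± 1.02). AT1G02360, of the chitinase family, stood at 2.06 ± 0.88, and AT5G47330, of the alpha/beta hydrolase family, at 1.97 ± 0.58. On the lower side, AT5G62210 was 13.0-fold lower with Tween 20 (log2 -3.70 ± 0.53), and UGT78D1, a flavonol rhamnosyltransferase, was 3.92-fold lower (-1.97 ± 0.22).

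Further named genes at 1 h differed in how closely the repetitions lay together. AT5G12050 was at 2.06 in IA and 1.95 in IB, and AT3G57460 at 2.09 and 1.78. AT1G19020 was at 3.37 in IA but 1.17 in IB, and AT1G53540, the small heat shock protein HSP17.6C, at 3.06 and 1.05. AT5G28630 was instead higher in IB, at 2.87 against 1.54. Among the lower transcripts, AT4G26790, of the GDSL lipase family, stood at -1.81 in both repetitions. AT5G62730 averaged -1.59 ± 0.20 and AT2G34340 -1.55 ± 0.31. The signal of AT5G62210 under Tween 20 was 2.2 and 2.9 units, far below the 40th percentile of its arrays, so its fold is uncertain. The water signals of AT5G59170, AT1G22810 and AT3G57460 and the Tween signals of AT4G26790, AT5G62730 and AT2G34340 also lay below that percentile in both repetitions, and the water signal of AT1G49000 did in IB (17.7 units) and in II (16.9 units), which makes their folds uncertain as well. Among transcripts without a gene name here, the 2 furthest above water stood at 4.47 and 2.69 and at 2.88 and 2.24, and the 2 furthest below at -2.09 and -1.77 and at -1.80 and -1.70.

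With a 2-fold difference in both IA and IB, as the study required, and a filter on dim signals chosen here, 109 probe sets were higher with Tween 20 and 19 were lower. The study stated 118 and 12, and its own filter is not given in the sources used here. Without the filter 373 were higher and 279 lower. With it, a 2-fold difference in the higher direction was met by 587 probe sets in IA alone and by 260 in IB alone, and 21 probe sets that were 2-fold higher in IA were 2-fold lower in IB, against 0 the other way round. With limma's moderated test and Benjamini-Hochberg adjustment, 0 of the 14345 probe sets passed at 1 h. The smallest adjusted p was 0.0673, shared by AT1G49000, AT5G12050, AT5G47330, UGT78D1 and others, and 1691 probe sets had an unadjusted p under 0.05, 931 of them higher and 760 lower. The same test passed 114 probe sets after quantile normalization, 75 with a pseudocount and 9 with a stricter filter on dim signals.

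**Figure D1:**
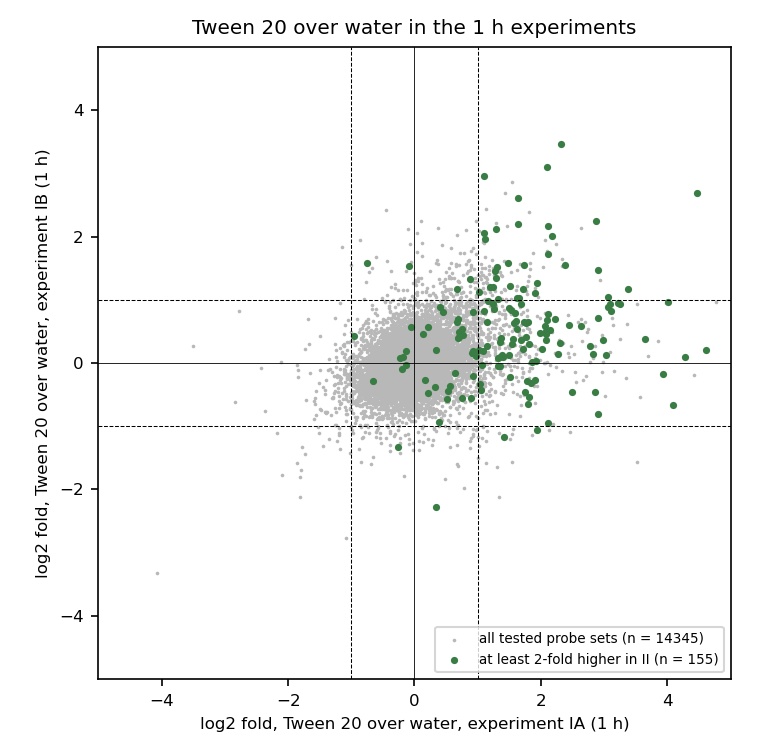
Log2 fold of Tween 20 over water in experiment IA (horizontal) and experiment IB (vertical), 1 point per tested probe set (n = 14345). Green points are the 155 tested probe sets that were at least 2-fold higher in experiment II at 2.5 h, and dashed lines mark 2-fold. Most green points lie to the right of 0, and their height on the IB axis is smaller, with medians of 1.49 in IA and 0.46 in IB for the full set of 165.

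After 2.5 h, genes were ranked among the 86 probe sets with 1 gene that were 2-fold higher and passed the filter on dim signals. The furthest above water was AT1G18680, 7.51-fold higher in experiment II (log2 2.91). XTH18, a xyloglucan endotransglucosylase/hydrolase of the cell wall, followed at 7.13-fold higher (2.83). AT4G28460 was 5.48-fold higher, although its signal was too low on 5 of the 6 arrays for it to enter the tests. UGT84A1, a glucosyltransferase of hydroxycinnamic acids, was 4.55-fold higher (2.19), and AT4G15690, of a plant-specific glutaredoxin group, 4.47-fold higher (2.16). AT3G04010 stood at 2.16, AT1G19020 at 2.04, AT3G50900 at 2.03, AT1G22810 at 1.96 and AT5G47330 at 1.69. The water signal of AT1G18680 in II was 3.9 units, below the 40th percentile of that array (23.8 units), so its fold and its rank are uncertain. The same holds for AT4G28460, UGT84A1, AT4G15690, AT3G04010 and AT1G22810, with water signals of 10.3, 8.0, 7.4, 15.9 and 10.9 units. XTH18 was above that percentile at 34.5 units, but its water signals in IA and IB were 281.2 and 346.5 units. Its Tween signal in II, 246.1 units, was below both of these, so its fold in II lay in a low water signal. Among the 18 probe sets with 1 gene that were 2-fold lower and passed the filter, the lowest were AT4G26790 (-1.73), AT4G02850 (-1.60), AT3G26760 (-1.42), AT5G15780 (-1.39) and AT4G01410 (-1.37). All of these except AT5G15780 were below the 40th percentile of the Tween array.

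At 1 h, XTH18 was at 1.33 in IA and -0.05 in IB. AT3G04010 was at 2.50 and -0.45, with the dimmer signal of each pair below the 40th percentile. Both signals were below it for AT1G18680 and AT4G15690 in IA and for UGT84A1 and AT5G15780 in IB, so these folds are not given. In the other repetition AT1G18680 was at 0.21, AT4G15690 at 1.58 with a dim water signal, UGT84A1 at 1.11 and AT5G15780 at -0.45. Of the other lower genes, AT4G02850 was at -1.57 in IA, with a dim Tween signal, and at -0.66 in IB. AT4G01410 was at 0.01 and -0.53. AT3G26760, with both signals dim in IA, was at 0.29 in IB with a dim water signal. With a 2-fold difference and the same filter, 165 probe sets were higher and 37 lower at 2.5 h, against 1275 and 1086 without the filter, where the study stated 137 and 11. Testing this pair against the spread of the 1 h pairs, limma passed 0 probe sets, with a smallest adjusted p of 0.998 and 586 probe sets at an unadjusted p under 0.05, and each of these folds therefore has no replicate check.

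Over the 3 experiments, 146 probe sets rose with Tween 20 and 15 fell in limma's paired test at an adjusted p under 0.05. All 146 were higher and all 15 were lower in each of the 3 pairs, but the test itself favours probe sets whose 3 folds lie close together. AT3G50900 rose by 3.88-fold, with log2 folds of 2.12, 1.72 and 2.03 in IA, IB and II (estimate 1.96 ± 0.13, SE, adjusted p = 0.0139). AT1G49000 rose 4.78-fold (2.26 ± 0.27, adjusted p = 0.0234), AT1G19020 4.57-fold (2.19 ± 0.36, adjusted p = 0.0450) and AT1G22810 4.31-fold (2.11 ± 0.26, adjusted p = 0.0261). AT4G26790 fell, with an estimate of -1.78 ± 0.19 (adjusted p = 0.0214), as did AT2G34340, at -1.71 ± 0.28 (adjusted p = 0.0450), although both its signals in II were below the 40th percentile. The calls of AT1G19020 and AT2G34340 were lost with median centring (adjusted p = 0.0610 and 0.0553) and with quantile normalization (0.0582 for both).

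Further named genes rose as well. PUB22, a U-box ubiquitin ligase of immune signalling, rose by 1.43 ± 0.12, with 1.28, 1.45 and 1.56 in IA, IB and II. AT1G61360, an S-locus lectin receptor kinase, rose by 1.35 ± 0.12, and AT1G65690, of the NDR1/HIN1-like family, by 1.46 ± 0.12. AT5G12420, an acyltransferase related to the wax ester synthase WSD1, rose by 1.74 ± 0.18, AT5G47330 by 1.88 ± 0.17 and AT2G46150 by 1.43 ± 0.19. The log2 estimates of the 146 probe sets that rose ran from 0.46 to 3.02. Their median log2 folds were 1.14 in IA, 1.09 in IB and 0.85 in II. Those of the 15 that fell were -1.20, -0.98 and -0.77. A name from 1 gene was at hand for 65 of the 146 and 10 of the 15. The largest estimate belonged to a probe set without a gene name (3.02 ± 0.44, adjusted p = 0.0351). These counts rest on each of the pairs IA and II and on the pairing, since 0 probe sets passed without IA, 0 without II and 0 with no experiment block, while 730 passed without IB. They also rest on the filter and the variance trend, with 0 passing unfiltered and 2 without the trend, and in simulated data 5.22% or 15.9% of such calls were false, depending on the noise model.

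**Figure D2:**
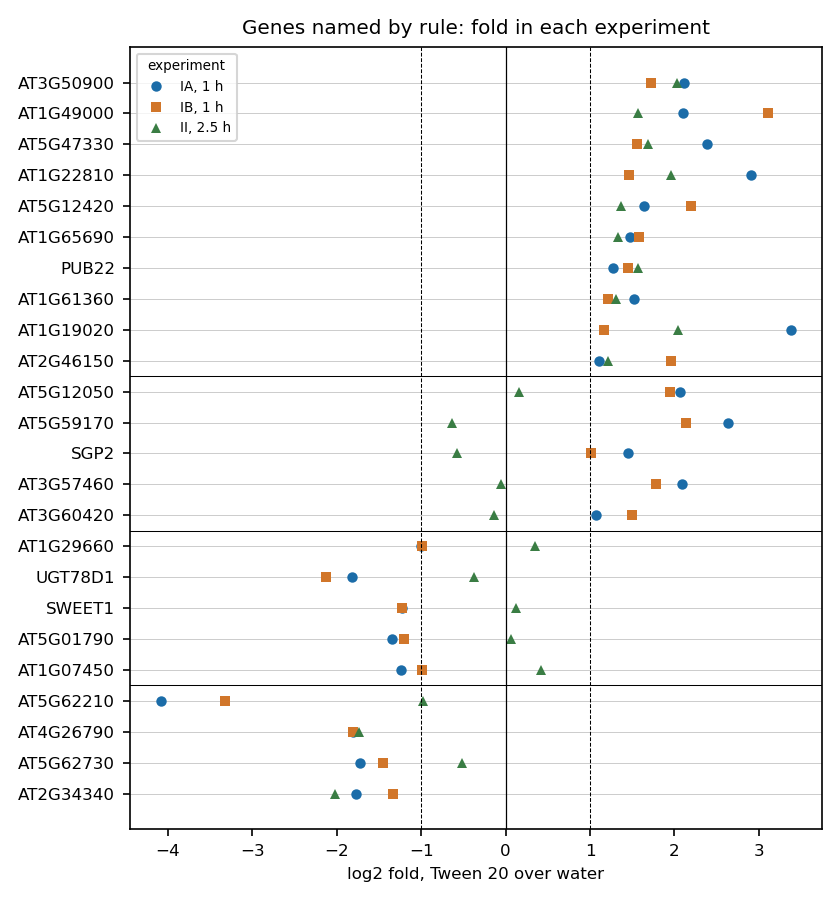
Log2 fold of Tween 20 over water in each experiment for 24 genes, 1 point per experiment and gene, with dashed lines at 2-fold. From top to bottom the blocks hold the 10 genes highest in all 3 pairs, the 5 lowest and the 5 highest by the difference of 2.5 h from 1 h, and 4 further genes lower at 1 h. The genes of the top block lie above 1 in every pair, from 1.11 for AT2G46150 in IA to 3.37 for AT1G19020 in IA.

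The sets that met the 2-fold criterion at the 2 times shared more members than independent sets would. Among 13310 probe sets bright in all 3 pairs, 98 were higher at 1 h and 137 at 2.5 h, and 29 were higher at both, against 1.01 for independent sets (odds ratio 50.9, 95% interval 30.5 to 83.5, two-sided Fisher's exact test, p = 3.53e-35). The study stated 38. The odds ratio was 6.14 with no filter, where 95 were higher at both times, 21.1 with IB alone as the 1 h set and 108 with IA alone. The 29 include AT3G50900, AT1G49000, PUB22, AT1G61360 and AT1G65690. Of 17 and 26 lower probe sets, 2 were shared, AT4G26790 and a probe set without a gene name, against 0.0332 for independent sets (exact p = 0.00049). With the filter at the 60th percentile 0 were shared, and the Tween signals of AT4G26790 were below the 40th percentile in all 3 pairs. Probe sets are not independent of each other, so these p-values describe the arrays only. Most of the 1 h set also lay above water later, as 101 of its 109 members were above 0 in II, with a median of 0.75.

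The reverse comparison depended on the experiment. The 165 probe sets higher at 2.5 h had a median log2 fold of 1.49 in IA and 0.46 in IB, and 114 of them were 2-fold higher in IA, 33 were 2-fold higher in IB and 4 were 2-fold lower in IB. Across all tested probe sets the folds of IA and II correlated more closely (Pearson's r = 0.513, Spearman's rho = 0.410) than those of IA and IB (0.330 and 0.275) or IB and II (0.203 and 0.126), with probe sets, which are not independent replicates, as the units. The treatment text of the labels names 2.5 h for IA, against its titles, and its collection time was not tested here. Experiment IB also stood apart in some control probe sets. The log2 ratio of the 3' to the 5' actin signal was 2.94 and 2.76 on its water and Tween arrays, against 4.13 and 4.26 in IA and 4.0 and 4.02 in II. Within the pairs, Tween minus water, this ratio differed by 0.13 in IA, -0.18 in IB and 0.02 in II, and that of GAPDH by -0.14, 0.26 and -0.16. By the ubiquitin ratio it was instead II that stood apart. Its water and Tween arrays were at 1.71 and 1.81, against 0.92 and 1.12 in IA and 1.00 and 0.91 in IB.

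Genes were ranked by the statistic of the difference between the effects at 2.5 h and 1 h. AT5G12050 stood at 2.06 and 1.95 after 1 h and at 0.16 after 2.5 h, a difference of -1.84 ± 0.27 (SE), and AT3G57460 at 2.09 and 1.78 and then -0.05 (-1.99 ± 0.39), where both signals in II were below the 40th percentile. AT5G59170 was at 2.64 and 2.14 and then at -0.64 (-3.03 ± 0.52), with signals of 39.8, 29.1 and 26.5 units in IA, IB and II under Tween 20 and of 6.4, 6.6 and 41.3 units under water. Its difference therefore lay mainly in the water arrays. SGP2, a small GTP-binding protein, went from 1.45 and 1.02 to -0.57 (-1.81 ± 0.32), and AT3G60420 from 1.07 and 1.5 to -0.14 (-1.42 ± 0.31). In the other direction, SWEET1, a sugar transporter, was at -1.22 and -1.23 after 1 h and at 0.13 after 2.5 h (1.36 ± 0.26). UGT78D1 went from -1.81 and -2.13 to -0.37 (1.60 ± 0.28), AT1G29660 from -1.0 and -0.99 to 0.35 (1.34 ± 0.21), AT5G01790 from -1.35 and -1.21 to 0.06 (1.34 ± 0.27) and AT1G07450 from -1.24 and -0.98 to 0.41 (1.52 ± 0.31). By size alone, the named genes AT5G62210 (2.72 ± 0.69), AT1G18680 (2.63 ± 0.60), XTH18 (2.2 ± 0.56) and AT4G15690 (1.75 ± 1.35) differed more in this direction, and all of them except XTH18 had dim signals. In the negative direction AT5G15780 (-2.38 ± 1.11), with dim signals in IB, lay beyond all those listed except AT5G59170. AT5G28630 (-1.57 ± 0.55), AT3G26760 (-1.56 ± 0.52) and AT1G02360 (-1.47 ± 0.53) lay beyond AT3G60420. None of these differences passed limma's interaction test after adjustment, in which 0 of 14345 probe sets passed, the smallest adjusted p was 0.998 and 356 probe sets had an unadjusted p under 0.05. Among probe sets with 1 gene, the smallest unadjusted p of this test was 0.000554, for AT5G12050, and time cannot be separated from experiment II.

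Of the gene lists fixed before the data were examined, the UDP-glycosyltransferases and the salicylate and immune genes stood higher as groups only in camera with a preset correlation, and the adjusted p was 0.505 and 0.279 with an estimated correlation. The list held 17 UDP-glycosyltransferases, which attach sugars to hormones and foreign compounds, and 7 of them were tested. Of these 7, 6 had an estimate above 0 over the 3 experiments, with a median of 0.63. UGT73B5 was at 3.36, 0.62 and 0.80 in IA, IB and II, UGT73B4 at 2.77, 0.27 and 1.27 and UGT87A2 at 0.42, 0.23 and 0.34. These 3 passed when adjusted over the list alone, and 0 members passed over all genes tested. The median of the list was 1.61 in IA, 0.23 in IB and 0.44 in II. limma's camera gave the list an adjusted p of 0.00121 with the preset correlation and of 0.505 with an estimated correlation.

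The 3 tested salicylate and immune genes, of 21 in the list, were higher in every pair. WRKY6, a transcription factor of senescence and defence, was at 1.99, 0.72 and 0.94, WRKY53 at 0.44, 0.81 and 1.02, and the glutaredoxin GRX480 at 1.84, 0.28 and 0.91. All 3 passed when adjusted over the list alone and 0 passed over all genes tested (adjusted p = 0.0751, 0.0673 and 0.147). camera gave an adjusted p of 0.000302 with the preset correlation, and the adjusted p was 0.279 with an estimated correlation. That correlation was estimated at -0.20 here, so correlation between the members did not raise the p. It was 0.94 for the UDP-glycosyltransferases. At 1 h alone both lists had an adjusted p of 0.000934 with the preset correlation, and the adjusted p was 0.602 with an estimated correlation.

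The other lists with enough tested members did not pass. The redox, glutathione transferase, and abscisate and cold lists held 16, 38 and 18 genes. Most of these were not tested, so the values below do not stand for the whole lists. In the redox list, NDB2, an alternative NADH dehydrogenase of mitochondria, was at 1.03, 0.31 and 0.45 and was the 1 member that passed when adjusted over the list alone, with a list median of 0.27 over 4 genes (adjusted p = 0.136). AT2G21640 was at 1.25, -0.22 and 0.39, and the glutathione reductase GR1 at 0.02, -0.13 and -0.01. The 5 glutathione transferases had a median of -0.14 (adjusted p = 0.209), with GSTU20 at -0.11, -0.34 and -0.19, GSTU18 at -0.37, -0.11 and -0.30 and GSTU27 at -0.23, -0.15 and -0.06. The 4 abscisate and cold genes had a median of -0.18 (adjusted p = 0.209), with COR47 at -0.30, -0.59 and -0.10, COR15A at -0.01, -0.43 and -0.19 and COR15B at -0.58, -0.21 and 0.37. In these 3 lists 0 members passed over all genes tested, and in the last 2 none passed when adjusted over the list alone.

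**Figure D3:**
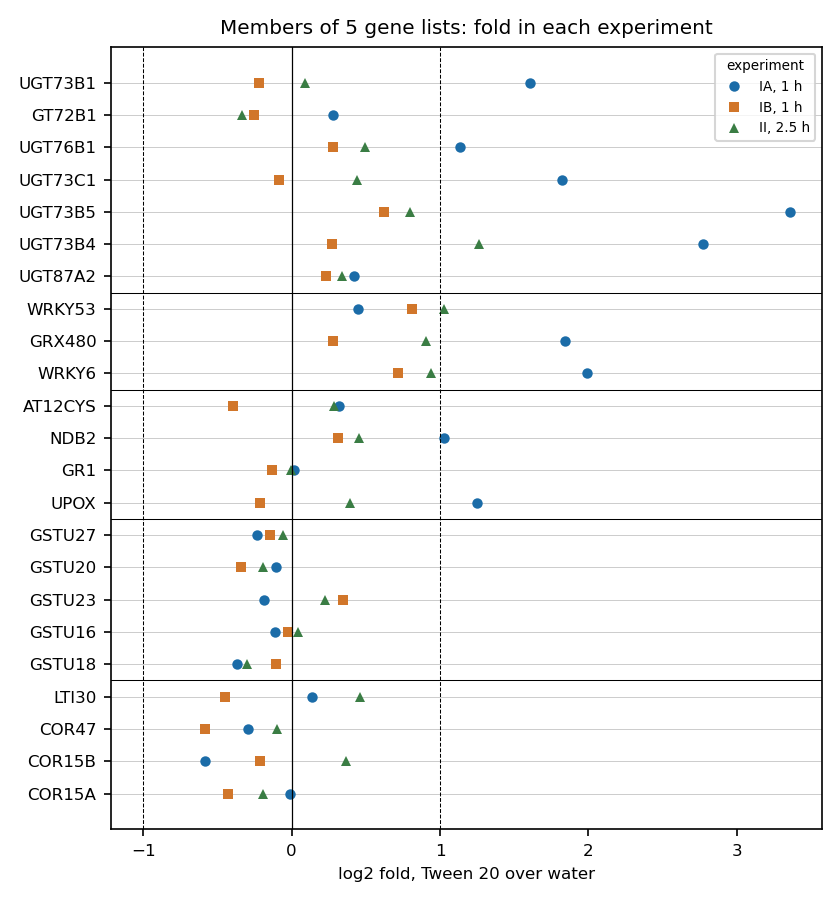
Log2 fold of Tween 20 over water in each experiment for the 23 tested members of 5 gene lists, 1 point per experiment and gene, with dashed lines at 2-fold. From top to bottom the blocks are UDP-glycosyltransferases, salicylate and immune genes, redox genes, glutathione transferases, and abscisate and cold genes. The IA points of the first block reach 3.36 for UGT73B5, while its IB points stay at or below 0.62.

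In the remaining lists 1 or 2 members were tested, which is too few for a test of the group, and 0 of these members passed over all genes tested. The alkenal reductase AER was at 1.90, 0.08 and 0.83 in IA, IB and II, and the zinc finger repressor STZ, also called ZAT10, at 2.56, -0.31 and 0.84. The calmodulin-like CML38 was at 2.67, -0.26 and 0.42, the first with a water signal of 13.5 units, below the 40th percentile. BZIP60, a transcription factor of the unfolded protein response, was at 1.53, 0.26 and 0.82, and the co-chaperone ATERDJ3B at 0.86, -0.23 and 0.68. ATHSP22.0, a heat shock protein of the endoplasmic reticulum, was at 3.01, -0.52 and -0.08, the last from signals below the 40th percentile. The other tested heat shock gene, AT1G53540 (HSP17.6C), was at 3.06, 1.05 and 1.16 (limma's adjusted p = 0.0856 over the 3 experiments). The auxin-conjugating enzyme GH3.3 was at 1.95, 1.04 and 0.72 (adjusted p = 0.0673 over the 3 experiments) and its relative WES1 at 0.38, 0.48 and 0.24. The water signal of GH3.3 in IA, 21.8 units, was just below the 40th percentile. The jasmonate synthesis gene OPCL1 was at 1.12, -0.64 and 0.58, and the defensin PDF1.2 at -0.96, -0.24 and -0.83 (adjusted p = 0.104). The transporter gene AT2G04050 was at -0.29 in IB, with dim signals in IA and II, and the wax ester synthase WSD1 at -0.80, 1.01 and 0.01.

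No marker of leaf function, time of day or another organ passed the test. The photosynthesis genes LHCB4.1 and RCA had estimates of -0.05 and -0.02 over the 3 experiments. The clock gene GI was at -0.46, -0.06 and 0.13. The root marker PYK10 was at -0.05, -0.60 and 0.14. The reference genes AT4G34270 and AT2G28390 had estimates of -0.07 and -0.16. No probe set was at hand for the lists of cytochromes P450 and of flower and seed markers.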

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

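The test of the difference between times was chosen before the data were examined, and the requirement of a 2-fold difference in both 1 h pairs, by which these genes were picked, was set after the result was seen.

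In 6 named genes both 1 h pairs moved at least 2-fold 1 way and the 2.5 h pair lay on the other side of 0. For AT3G60420, AT3G57460, SWEET1 and AT5G01790 the 2.5 h value was close to 0 and shows no reversal. Both signals of AT3G57460 in II were also below the 40th percentile. AT5G59170 was at 2.64 and 2.14 in IA and IB and at -0.64 in II, and its water signals of 6.4 and 6.6 units at 1 h were below the 40th percentile of their arrays. SGP2 was at 1.45 and 1.02 and then at -0.57, AT3G60420 at 1.07 and 1.5 and then at -0.14, and AT3G57460 at 2.09 and 1.78 and then at -0.054. SWEET1 was at -1.22 and -1.23 and then at 0.13, and AT5G01790 at -1.35 and -1.21 and then at 0.064. limma's interaction test gave an adjusted p of 0.998 for each of them, so the differences did not pass, and the 2.5 h values rest on 1 pair. Among all probe sets that were 2-fold at 1 h, 8 of the 109 higher ones lay below 0 in II, 2 of the 19 lower ones lay above 0, and 0 of the higher ones were 2-fold lower in II. No explanation was tested for these genes, since experiment II differs from the others in time and in being another experiment.

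The control probe set for 25S ribosomal RNA, which enters no comparison, was 1.55-fold higher with Tween 20 than with water in experiment IB, at 1252 against 808 units. It was at 1422 against 1361 units in IA and at 638 against 840 units in II.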

How the results depend on the processing

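Array weights and sets of equal size were added after the data were seen, and all other settings were chosen before. Over the 3 experiments, median centring passed 116 probe sets (7 of them lower), all among the 161, quantile normalization 146, all among the 161, the 60th percentile filter 159 with 136 shared, the pseudocount 170 with 158 shared and array weights 203 with 159 shared. No filter passed 0 higher and 0 lower, with more probe sets tested, a smallest adjusted p of 0.120 and 2567 probe sets at an unadjusted p under 0.05. No intensity trend passed 1 and 1. Fits without the replicate block, which ignore the pairing, passed 0 higher and 0 lower, with 614 at an unadjusted p under 0.05. Leaving out an experiment gave 0 to 574 higher and 0 to 156 lower probe sets, with 0 without IA or II (1215 and 1691 at an unadjusted p under 0.05) and 730 in all without IB, of which 160 were among the 161. Fewer arrays were tested in each of these fits, and the cause of the rise without IB, as of the other changes, was not tested.

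At 1 h, where 0 passed, quantile normalization passed 102 higher and 12 lower, the pseudocount 65 and 10 and the 60th percentile filter 7 and 2. With no block and each 1 h array left out in turn, 0 to 49 higher probe sets passed, the 49 without the Tween array of IB. Median centring, no filter, no trend and no block passed 0 at 1 h. At 2.5 h and for the difference between times, limma passed 0 under every alternative run.

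With no signal filter the 2-fold counts were 373 higher and 279 lower at 1 h, 1275 and 1086 at 2.5 h and 95 and 63 at both times. The 60th percentile gave 12 lower at 1 h, 89 higher and 14 lower at 2.5 h and 0 lower at both times. The pseudocount gave 98 and 14 at 2.5 h and 18 and 1 at both times. Leaving out IA or IB gave 260 to 587 higher and 116 to 163 lower at 1 h, and 33 to 114 higher and 4 to 7 lower at both times. Median centring and quantile normalization kept all of these counts within 1.5 times. With sets of equal size, the 137 largest folds of each 1 h pair, IA shared 55 probe sets with II and IB shared 23, against 1.41 for independent sets.

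Leaving out an experiment could not reverse the genes that passed over the 3 experiments, since their sign was the same in every pair. Of the single genes, none that passed over the 3 experiments reversed under the other settings. Those that changed sign when an experiment was left out were near 0 or differed between experiments, with ranges of log2 estimates of -0.031 to 0.85 for OPCL1, -0.30 to 1.47 for ATHSP22.0, -0.40 to 0.079 for COR15B, -0.26 to 0.036 for GI, -0.069 to 0.0056 for GR1, -0.39 to 0.51 for WSD1, -0.078 to 0.010 for LHCB4.1, -0.076 to 0.0061 for RCA, -0.32 to 0.044 for PYK10 and -0.17 to 0.054 for AT4G34270. Across genes and alternatives 720 comparisons kept direction and side of the threshold, 33 newly passed, 51 no longer passed and 11 reversed. For gene lists 29 kept and 6 no longer passed, all with an estimated correlation or fry (with fry, adjusted p = 0.462 for UDP-glycosyltransferases and 0.119 for immune genes). No scaling reversed the median of a list described in the results. Dim signals limit the 2-fold counts, which were higher with no filter.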

Other observations

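The families and genes in this part, and all tests in it except limma's paired test and the splits of the arrays, were chosen after the results were seen, and the bounds for the families were changed after that as well.

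Further genes that passed limma's paired test over the 3 experiments were named after their values were seen. SD1-29, a receptor kinase of the S-locus lectin group, rose by 1.12 ± 0.12 (SE, adjusted p = 0.0226), AT1G61370, with the neighbouring code, by 0.80, AT3G09830, a receptor-like cytoplasmic kinase, by 1.05 and AT4G08850, a leucine-rich repeat receptor kinase, by 0.98. The pirin gene PRN rose by 1.44, AT4G01700, of the chitinase family, by 1.06, and AT1G17860, a protease inhibitor of the Kunitz type, by 1.38. The pectin methylesterase ATPMEPCRB rose by 1.21, and AT1G67750, a pectate lyase, was at -1.15. The sugar transporter SAG29 was at -0.88. The calls of AT1G61370, AT1G17860, ATPMEPCRB and SAG29 were lost with median centring (adjusted p = 0.0556, 0.0641, 0.0610 and 0.0579) and with quantile normalization (0.0522, 0.0608, 0.0581 and 0.0569). AT1G29670, of the GDSL lipase family, rose by 0.93 while its neighbour AT1G29660 stood at -1.0, -0.99 and 0.35 in IA, IB and II.

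Among 8 gene families set apart after the values were seen, 3 stood higher in camera with the preset correlation and none of these held with an estimated correlation (adjusted p = 0.237, 0.237 and 0.365). The correlation was estimated at -0.115 for the berberine bridge enzyme-like oxidases and -0.203 for the WRKY factors, so it did not raise their p. With 2 residual degrees of freedom behind the estimated setting, this loss does not decide whether the families moved. Of 9 tested berberine bridge enzyme-like oxidases, which include enzymes that oxidise cell wall oligosaccharides, AT4G20830 rose by 1.15 (adjusted p = 0.0139 over all genes tested), and AT4G20860 (1.23), AT1G26420 (1.02) and AT1G30700 (1.60) passed only when adjusted over the list alone. The adjusted p of this family was 0.00048 with the preset correlation and 0.237 with an estimated correlation. A shared response of the family may lie behind these values, a hypothesis the test leaves open. fry, which asks only whether a set's genes move 1 way, gave an adjusted p of 0.0256 for this family and for the WRKY factors. The 5 WRKY factors had the same adjusted p values in camera, with WRKY22 at 1.05 and WRKY47 at 0.50 beside WRKY6 and WRKY53, and 4 passed when adjusted over the list alone. Of the 5 calmodulin-like genes, CML42 rose by 1.31 (adjusted p = 0.0493, but 0.0663 with median centring and 0.0609 with quantile normalization), and the family's adjusted p was 0.00819 with the preset and 0.365 with an estimated correlation. The 27 genes named UGT had a median of 0.01, with 14 above 0 and 13 below. Their adjusted p was 0.201 with the preset and 0.660 with an estimated correlation in camera, so no common direction of the wider family was found. The glutathione transferases, CYP71 cytochromes and xyloglucan hydrolases did not pass.

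The probe sets higher at 2.5 h were less far above water in IB, where their median log2 fold was 0.305 times that in IA. By the titles and the design text IA and IB were both 1 h repetitions, so no biological explanation of this pattern was tested. The treatment text of the labels, however, names 2.5 h for the samples of IA, and whether IA was collected at that time was not tested. The tables argue against a narrower signal range in IB, whose log2 range was 1.01 times that of IA, against exchanged or mislabelled IB arrays, since 109 probe sets 2-fold higher in IA were 2-fold higher in IB and 21 lower, a ratio of 5.19, and against RNA degradation that differs between the arms, since the largest difference of 3' to 5' log2 ratios was 0.264. It stays open whether a higher level in the water-sprayed plants of IB was part or all of it, because the set's median log2 difference between the water arrays, IB minus IA, was 0.209 above that of all tested probe sets, between the bounds set for and against, and 33 of the 165 were at least 2-fold higher there, 20.0% against 4.65% of all tested ones. The set was also lower on the Tween array of IB than on that of IA, with a median of -0.451 relative to all tested probe sets and 47 of 165 higher in IB, but with 1 array per arm this has no spread between arrays and decides nothing. Batch and experiment cannot be told apart, since IB also differed in its actin ratio, in its spike-in signals and in the wording of its protocol.

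Of the 10 splits of the 6 arrays into 3 against 3, with the experiment as a block, 1 gave as many calls as the 161 of the real split, namely the real split itself. The splits are too few for a share under 0.05, and those that parted only 1 pair are unlike the real split, which parts all 3. The highest count among the others was 19, in the splits that parted only the arrays of IA, and the splits that exchanged the arms of 1 of the 3 pairs gave 0.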
